A study of Mus musculus with 4 samples.

How the data were processed

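The data were RNA-seq libraries of mouse bone marrow-derived macrophages transfected with a GapmeR against Malat1 or a negative control GapmeR, with 2 libraries per group. Per the labels' protocols, total RNA was extracted with a column kit, libraries followed the standard Illumina procedure and sequencing used a Genome Analyzer IIx. The deposited values were whole-number counts of reads per gene for each library, not normalized. Per the submitters' processing notes the tools included bcl2fastq 2.18.0.12, STAR 2.5.2b, HTSeq 0.6.0 and DESeq2, with the genome build mm10. The annotation release, the strandedness of the kit and the overlap mode of the counting were not given in the sources used here. Where overlapping genes share reads, or where a library does not mark strand, counts of overlapping and antisense genes are therefore uncertain.

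The count table held 48795 genes under versioned Ensembl identifiers. The counter's summary lines, which name no gene, held 24% and 23.7% of all counts in control libraries 1 and 2 and 24.5% and 24.4% in knockdown libraries 1 and 2, and were left out of library sizes and tests. Most of these were reads aligned at several places, at 13.1%, 13%, 14.4% and 13.3% of all counts in the same order, so that genes with near-identical copies are undercounted. Genes were matched to GENCODE M21 (GRCm38, the assembly also called mm10) by identifier without its version. A symbol was found for 48349 genes and none for 446, and 41341 versioned identifiers matched. Positions, exonic lengths (the union of a gene's exons), GC content and neighbouring genes came from that annotation.

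Groups were taken from the transfection named in the labels. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which can be technical. The libraries of each group were compared with each other first. Their counts differed by more than sampling noise (chi-square per gene 3.85 for the controls and 49.5 for the knockdown libraries), and each was counted as 1 replicate. The median absolute log2 difference between libraries was 0.09 for the controls and 0.26 for the knockdown libraries.

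Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with the default filter of filterByExpr by group, which left 13706 genes, and libraries were scaled with TMM. Changes were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) between the groups with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The common dispersion was 0.0156, which is a biological coefficient of variation of 0.125. CPM values are TMM-scaled, and means are given with the SD of 2 libraries. An exact permutation test of 2 libraries against 2 cannot reach a two-sided p under 0.333, so single genes were tested with the spread shared across genes. Groups did not overlap in 50% of the tested genes, where chance gives 33.3%. Floors at 3 counts cover counting error only. Bootstrap intervals of a median cover the spread between genes, not that between libraries.

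A total of 31 gene lists, the rule for the genes named in the text, the tests and all alternatives except those said to be chosen later were fixed before the data were examined. The lists were chosen to fit the cell type, the treatment and the known subject of the study, macrophage activation and mitochondrial metabolism. A call within them, such as that of Clec16a, is therefore not an independent prediction. The lists covered inflammatory, interleukin-4, interferon and profibrotic macrophage genes, oxidative phosphorylation, mitochondrially encoded mRNAs, pyruvate and tricarboxylic acid cycle, glycolysis, autophagy, the neighbours of Malat1, nuclear speckle and SR proteins, p53 targets, the cell cycle, the stress response, cholesterol synthesis and efflux, NRF2 targets, hypoxia, lysosome, antigen presentation, immediate early genes, histones, ribosomal proteins and macrophage identity. They also held markers of neutrophils, dendritic cells, lymphocytes, fibroblasts, erythroid cells and megakaryocytes, mast cells and basophils, and osteoclasts. The 28 lists with 5 or more tested members were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation, and fry, which tests a list on its own, were run beside it. With an estimated correlation 0 of the 28 lists passed. The estimated form takes its p-value from the few residual degrees of freedom that 4 libraries leave, so hardly any list could pass after adjustment. Not passing it therefore does not show that correlation between genes produced a result with the preset value, and that question stays open. Members were also counted with p-values adjusted over the list alone.

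Named genes were Malat1, Neat1, Clec16a, Mpc1 and Mpc2, the 10 genes per direction with the largest fold among those past the threshold with a mean of at least 5 CPM and with both knockdown libraries on the same side of both controls, and up to 4 members per list with the smallest p. Genes without a symbol in the annotation were not named, and the values of some listed genes are not reported here. A gene was said to have an expressed gene upstream where a gene at 20 CPM or more ended within 10 kb of its start on the same strand, a measure chosen after the data were seen.

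The alternatives were size factors by the median of ratios, upper-quartile factors, library size only, no filter on low counts, a filter of 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, a robust quasi-likelihood fit, the replicate number as a block, each library left out in turn, thresholds of 0.01 and 0.1 and a minimum fold of 1.2 (glmTreat). An alternative added after the data were seen used offsets per library, from loess fits on exonic length and GC content, which 99.7% of the tested genes had. The test was checked on simulated counts for the same 13706 genes, drawn from the means and library sizes of these samples. It recovered 31.3% of 67 genes changed by 1.5-fold, 85.1% of 67 changed by 2-fold and 100% of 66 changed by 4-fold, with 12 false calls. Changed genes were drawn only from those above a set mean CPM, and both groups were given the same spread. The recovery therefore does not cover the lowest genes, and neither figure covers the wider spread between the knockdown libraries. Each simulated gene had the trended dispersion of its level, with no variation of its own around that trend. In the data genes did vary around it (prior degrees of freedom 4.6), so recovery there may be lower. Camera called 0 of 20 random lists. Genes were simulated independently of each other, so this cannot show how camera behaves where genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.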

Results

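Bone marrow cells of C57BL/6 mice were grown into macrophages for 5 days with 50 ng/ml macrophage colony-stimulating factor (M-CSF). The cells were then transfected with an antisense LNA GapmeR, a chemically modified oligonucleotide that directs RNase H to cut a chosen RNA in the nucleus. The GapmeR was directed either against Malat1, at 50 nM, or, as a negative control, against no stated target. No dose was recorded for the control GapmeR. Total RNA taken 48 h after transfection was sequenced, with 2 libraries per group and 4 in all. Reads assigned to genes came to 26202418 and 30800827 in control libraries 1 and 2, and to 28803829 and 33636030 in Malat1 knockdown libraries 1 and 2. At these depths 3 counts in a library equal between 0.0869 and 0.117 on the counts-per-million scale (CPM), and 13706 genes had enough counts to be tested. The groups separated along the first principal component, which held 66.3% of the variance of log CPM. Knockdown library 1 lay further from the controls (score 43.7) than knockdown library 2 (12.7), against -28.6 and -27.9 for the control libraries.

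The comparison asked which transcripts of a macrophage change when Malat1, an abundant long noncoding RNA of nuclear speckles, is depleted. Malat1 (ENSMUSG00000092341.2, a single-exon lincRNA on the minus strand of chromosome 19, 5795690 to 5802672, mm10) was at 1274 and 1144 CPM in the control libraries. In the knockdown libraries it was at 24.6 and 31.0 CPM. The group means were 1209 ± 91.7 and 27.8 ± 4.55 CPM (SD, n = 2 each), so that Malat1 fell by 5.44 on the log2 scale (SE 0.17, adjusted p = 0.000139, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Neat1, the speckle-adjacent paraspeckle RNA encoded next to it on chromosome 19 (5824708 to 5845478), was at 1434 ± 51.5 CPM in control and 1452 ± 36.2 CPM in knockdown cells (SD, n = 2 each). Its log2 difference of 0.02 (SE 0.10) was within the spread between replicates (adjusted p = 0.944). Among the 15 tested members of a list of 18 genes next to Malat1, 0 rose and 0 fell by edgeR's quasi-likelihood test, and the same counts held when adjusted over the list alone, with 1 member at an unadjusted p under 0.05. Their median log2 difference was 0.03, and their mean of 0.27 was drawn up by Tigd3, at 0.0392 ± 0.0554 CPM in control and 0.435 ± 0.0819 CPM in knockdown libraries (SD, n = 2 each). The list did not stand apart from other genes (camera, adjusted p = 0.573).

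In the knockdown cells 134 genes passed the test at an adjusted p under 0.05, of which 102 rose and 32 fell. After Malat1 itself, the fall with the highest fold was that of Clec16a, an endolysosomal protein that acts in mitophagy with the E3 ubiquitin ligase Rnf41. Clec16a (ENSMUSG00000068663.13, chromosome 16, 10545339 to 10744878, plus strand) dropped from 29.98 ± 0.102 to 2.30 ± 0.972 CPM (SD, n = 2 each), a fall by 3.69 on the log2 scale (SE 0.26, adjusted p = 0.00641). Pi4ka, a lipid kinase that makes phosphatidylinositol 4-phosphate (chromosome 16, 17280351 to 17406314), was at 66.1 ± 1.54 CPM in control and 16.2 ± 1.51 CPM in knockdown cells (SD, n = 2 each), and fell by 2.03 on the log2 scale (adjusted p = 0.00347). Mgat5, which branches N-glycans (chromosome 1, 127205015 to 127488336), dropped from 88.1 ± 1.94 to 25.6 ± 7.95 CPM (SD, n = 2 each). Aoah, the enzyme that removes acyl chains from bacterial lipopolysaccharide (chromosome 13, 20794113 to 21036617), dropped from 164 ± 3.49 to 57.1 ± 6.91 CPM (SD, n = 2 each). With a filter of 5 CPM, Mgat5 did not pass (adjusted p = 0.0582, in a range of 1.55e-27 to 0.0582 over the alternatives). These 4 genes span 199540, 125964, 283322 and 242505 bp of the genome.

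The formyl peptide receptor gene Fpr1 fell by 1.61 on the log2 scale, the myeloid receptor gene Cd300e by 1.48, the immunoglobulin superfamily gene Igsf9 by 1.43 and the cyclin gene Ccnd2 by 1.39, with adjusted p-values between 0.0112 and 0.0294. Igsf9 (adjusted p = 0.0657, in a range of 1.19e-15 to 0.0657 over the alternatives) and Ccnd2 (0.059, 1.8e-12 to 0.059) did not pass with a filter of 5 CPM. B230118H07Rik fell by 2.07 (adjusted p = 0.0141). It overlaps Rag1 on its own strand and Rag2 on the other, and as it is not stated whether the counting used strand, its reads cannot be assigned with certainty. Mpc1 and Mpc2, the subunits of the mitochondrial pyruvate carrier, did not pass the test. Mpc1 was at 11.7 ± 1.95 CPM in control and 13.9 ± 0.149 CPM in knockdown cells (SD, n = 2 each, log2 difference 0.24, SE 0.16, adjusted p = 0.533). Mpc2 was at 20.9 ± 1.23 and 24.4 ± 4.74 CPM (SD, n = 2 each, log2 difference 0.22, SE 0.17, adjusted p = 0.563). Without knockdown library 2 the log2 difference of Mpc2 was 0.42, in a range of 0.009 to 0.42 over the alternatives. With 1 knockdown library left the spread rests on the control pair, so the side of the threshold there says little.

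**Figure D1:**
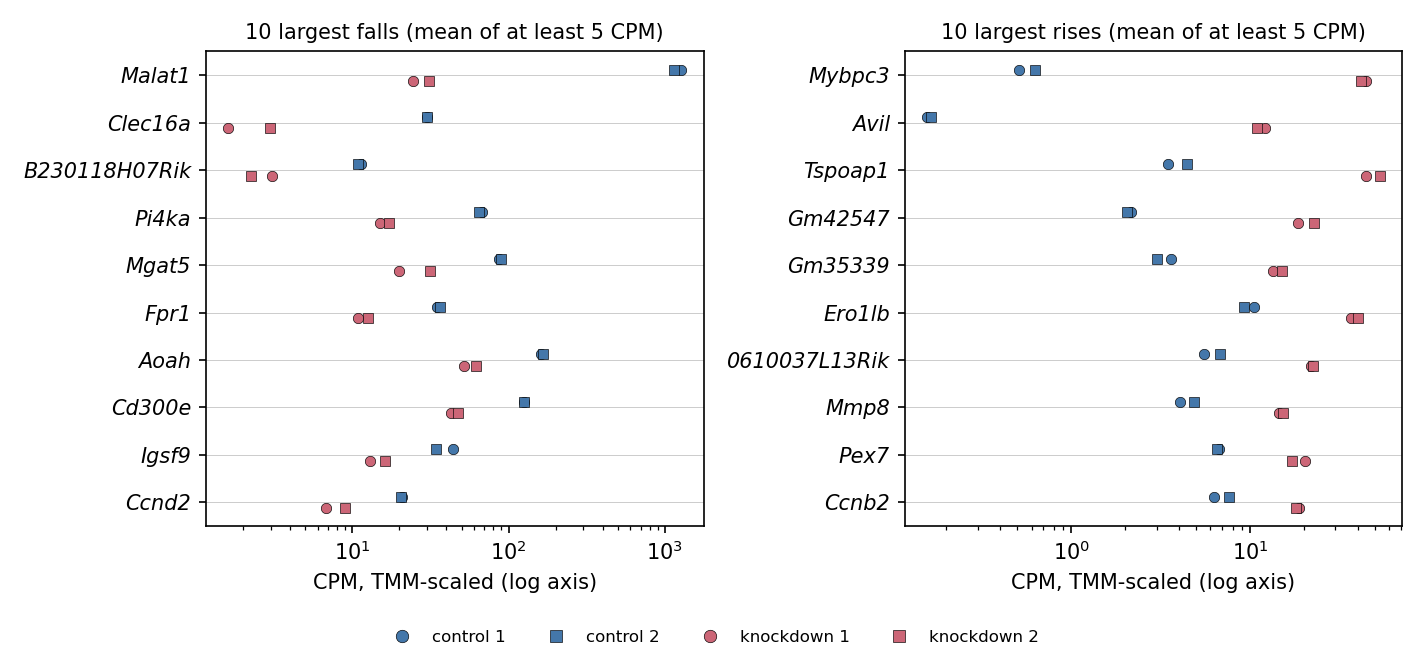
Expression in each of the 4 libraries (CPM after TMM scaling, log axis) of the 10 largest falls (left) and 10 largest rises (right). Genes were picked among those past the threshold with a mean of at least 5 CPM. Both knockdown libraries had to lie on one side of both control libraries, so the separation seen here was set by the choice. Blue symbols are control and red symbols knockdown libraries. Malat1 goes from 1274 and 1144 CPM to 24.6 and 31.0 CPM.

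Most genes that rose started from a low level. Mybpc3, which encodes the cardiac myosin-binding protein C (ENSMUSG00000002100.15, chromosome 2, 91118144 to 91136516, plus strand), was at 0.568 ± 0.0834 CPM in control and 43.4 ± 1.94 CPM in knockdown cells (SD, n = 2 each), a log2 rise of 6.23 (SE 0.18, adjusted p = 0.000139). Avil, which encodes the actin-binding protein advillin (chromosome 10, 127000709 to 127020994, plus strand), was at 0.161 ± 0.00591 and 11.6 ± 0.898 CPM (SD, n = 2 each), a log2 rise of 6.13 (SE 0.25, adjusted p = 0.000457). Both lie just downstream of genes that macrophages express on the same strand. Mybpc3 starts 2388 bp past the end of Spi1, which was at 563 CPM over the 4 libraries, and Avil 734 bp past the end of Ctdsp2, at 185 CPM. Avil also overlaps Tsfm on the other strand, so that part of its reads could not be assigned with certainty. Tspoap1, which encodes a protein that binds the mitochondrial translocator protein (chromosome 11, 87760541 to 87785928), was at 3.97 ± 0.686 CPM in control and 48.8 ± 6.30 CPM in knockdown cells (SD, n = 2 each), a log2 rise of 3.61 (adjusted p = 0.00138).

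Among the called genes with a mean of at least 5 CPM, the next rises were those of Gm42547 (log2 3.30), Gm35339 (2.10), the endoplasmic reticulum oxidase gene Ero1lb (1.96), 0610037L13Rik (1.84), the collagenase gene Mmp8 (1.74), the peroxisomal import receptor gene Pex7 (1.49) and the mitotic cyclin gene Ccnb2 (1.40), with adjusted p-values from 0.00203 to 0.0225. Of these, Gm35339 starts 52 bp past Maf1, 0610037L13Rik 2389 bp past Magoh and Ccnb2 3877 bp past Rnf111, each a gene at 20 CPM or more on the same strand. Of the 100 genes that rose and have an annotated position, 63 (63%) had such a gene ending within 10 kb upstream, against 11% of all tested genes. The share was 24.1% of the genes that rose without knockdown library 1 and 19% without knockdown library 2, when many more genes were called. Among the 62 that were under 2 CPM in control cells the share was 79%, and among the other 38 it was 36.8%.

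The number of changed genes moved with the knockdown library left out. It was 1812 without knockdown library 1 and 6751 without knockdown library 2, all 134 genes included each time, where the lone knockdown library is assumed to vary as the controls do. DESeq2 called 344 genes, 132 of the 134 among them.

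**Figure D2:**
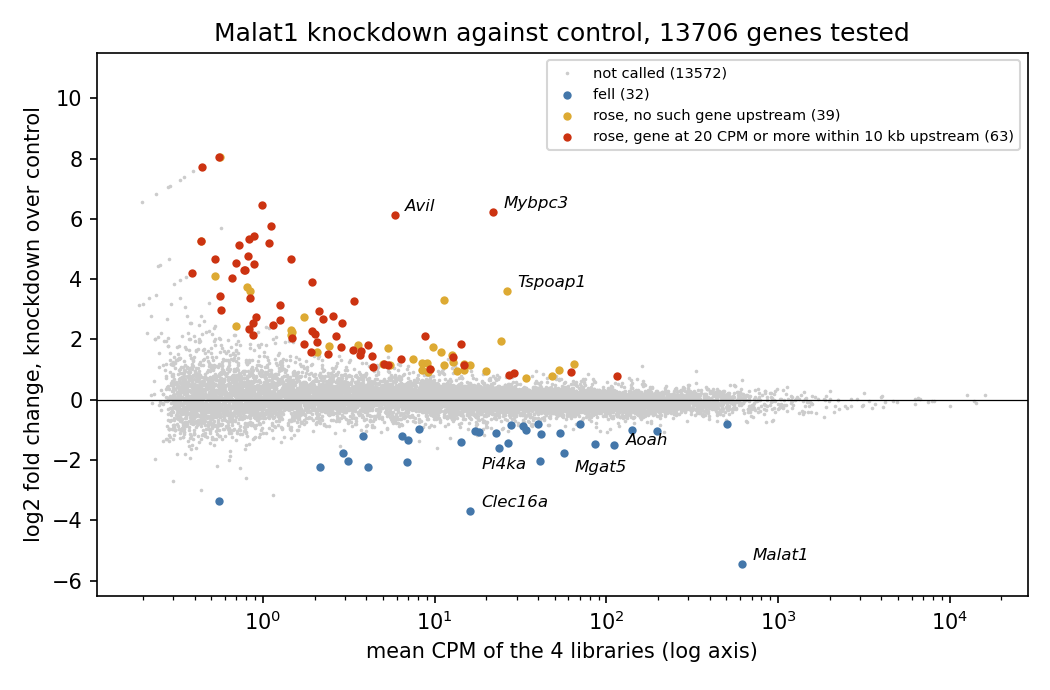
Log2 fold change (knockdown over control) of each of the 13706 tested genes against its mean CPM over the 4 libraries (log axis); grey points did not pass the test, blue points fell (32), and red and yellow points rose, with (63) and without a gene at 20 CPM or more within 10 kb upstream on the same strand. Rises lie mostly below 10 CPM and falls mostly above it, and the fitted fold of a gene with no counts in control depends on the prior count.

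The cell cycle genes had the highest median change of the 28 tested gene lists. Of 37 tested members 4 rose and 0 fell, and 23 rose when adjusted over the list alone. The median log2 difference of the list was 0.61, at 0.58 in knockdown library 1 and 0.73 in knockdown library 2. Ube2c, which tags mitotic proteins for degradation, was at 7.53 ± 0.964 CPM in control and 18.0 ± 2.39 CPM in knockdown cells (SD, n = 2 each, log2 rise 1.25, adjusted p = 0.038). Cdc20, the activator of the anaphase-promoting complex, was at 5.08 ± 0.0958 and 11.7 ± 1.61 CPM (SD, n = 2 each, log2 rise 1.21, adjusted p = 0.038). The other members past the threshold were Ccnb2 (log2 1.40) and the spindle gene Nusap1 (0.96, adjusted p = 0.0459). Nusap1 did not pass without control library 1 (adjusted p = 0.271) or control library 2 (0.0896), in a range of 3.51e-07 to 0.271 over the alternatives. With a filter of 5 CPM Nusap1 (adjusted p = 0.0787), Ube2c (0.0702, in a range of 1.13e-09 to 0.0702) and Cdc20 (0.0702, 2.34e-08 to 0.0702) did not pass. The list stood above other genes by camera with a preset correlation (adjusted p = 7.19e-19). It did not pass by camera with an estimated correlation (p = 0.0275, adjusted p = 0.634), a form with little power on 4 libraries.

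The 20 antioxidant genes controlled by the transcription factor NRF2 were all on the higher side in knockdown cells, with a median log2 difference of 0.41 (0.50 and 0.30 in the 2 libraries). A total of 0 members rose over all genes tested by edgeR's quasi-likelihood test, and 9 rose when adjusted over the list alone. Gclm, a subunit of the enzyme that starts glutathione synthesis, was at 41.9 ± 0.814 CPM in control and 67.2 ± 0.910 CPM in knockdown cells (SD, n = 2 each, log2 difference 0.68, adjusted p = 0.0517). Srxn1, which repairs oxidized peroxiredoxins, was at 53.3 ± 2.19 and 75.8 ± 5.86 CPM (SD, n = 2 each, log2 difference 0.51, adjusted p = 0.146), and Osgin1 at a log2 difference of 0.60 (adjusted p = 0.111). The list passed by camera (adjusted p = 4.63e-07), and not by the weaker form with an estimated correlation (adjusted p = 0.634). Genes of cholesterol synthesis and uptake had a median log2 difference of 0.25 (0.22 and 0.18) over 23 tested members, with 0 called over all genes and 0 adjusted over the list alone. Stard4 was at 12.3 ± 1.17 and 16.4 ± 1.92 CPM (SD, n = 2 each). This list passed by camera (adjusted p = 0.0116; adjusted p = 0.634 with an estimated correlation), but not without control library 2 (adjusted p = 0.0799, in a range of 0.00107 to 0.0799 over the alternatives), and its median was 0.16 with offsets for exonic length and GC content, which were chosen after the data were seen.

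Of the 35 type I interferon response genes 0 were called over all genes and 0 adjusted over the list alone, and 6 were on the higher side in knockdown cells. Their median log2 difference was -0.24 (-0.19 and -0.25 in the 2 libraries). Ifit2 was at 823 ± 107 CPM in control and 488 ± 78.2 CPM in knockdown cells (SD, n = 2 each, log2 difference -0.75, adjusted p = 0.102), and Rsad2 at 298 ± 38.1 and 209 ± 22.1 CPM (SD, n = 2 each, log2 difference -0.51, adjusted p = 0.206). The list passed on the lower side by camera (adjusted p = 9.34e-05; adjusted p = 0.801 with an estimated correlation), but not without control library 1 (median -0.11, adjusted p = 0.125, in a range of 1.3e-11 to 0.125 over the alternatives), against a median of -0.34 without control library 2. The inflammatory genes that lipopolysaccharide and NF-kB induce had a median of -0.28 (-0.28 and -0.11) over 25 members. Socs3, an inhibitor of cytokine signalling, fell from 35.5 ± 0.679 to 19.96 ± 1.24 CPM (SD, n = 2 each, log2 difference -0.83, adjusted p = 0.0429), and 5 members fell when adjusted over the list alone. Nfkbiz was at 230.2 ± 7.79 and 134 ± 19.4 CPM and Tnf at 10.3 ± 1.32 and 6.25 ± 0.172 CPM (SD, n = 2 each). The list passed by camera (adjusted p = 0.00227; adjusted p = 0.634 with an estimated correlation), but not without control library 2 (median -0.15, adjusted p = 0.177, in a range of 7.74e-06 to 0.177). With the scaling computed again, its median was -0.49 without knockdown library 2 and -0.11 without knockdown library 1. Socs3 did not pass without control library 1 (0.153) or 2 (0.221), nor with a filter of 5 CPM (0.0748), in a range of 4.18e-09 to 0.221.

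In 3 groups the lists moved with knockdown library 1. Nuclear-encoded oxidative phosphorylation genes (55 members, 0 called over all genes and 0 adjusted over the list alone) had a median log2 difference of 0.42 in knockdown library 1 and 0.02 in knockdown library 2. Their camera adjusted p was 0.00164 (adjusted p = 0.801 with an estimated correlation) and 0.924 without knockdown library 1, in a range of 3.41e-14 to 0.924 over the alternatives. Cytosolic ribosomal protein genes (77 members, 0 called over all genes and 0 adjusted over the list alone) had medians of 0.41 and -0.05, with an adjusted p of 0.00227 (adjusted p = 0.801 with an estimated correlation). Without knockdown library 1 they turned to the lower side (median -0.05, adjusted p = 0.0434, in a range of 8.23e-21 to 0.415). Genes of the integrated stress and unfolded protein responses (23 members, 0 called over all genes, 5 higher when adjusted over the list alone) had medians of 0.21 and -0.03, with an adjusted p of 0.0317 (adjusted p = 0.801 with an estimated correlation). They did not pass without knockdown library 1 (0.194) or control library 1 (0.1), in a range of 0.00709 to 0.343. Atf5 was at 15.8 ± 0.148 and 25.97 ± 3.2 CPM and Ddit3 at 39.1 ± 1.81 and 63.0 ± 12 CPM (SD, n = 2 each).

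Knockdown library 1 differed from the controls with gene length. Its median log2 difference was 0.27 in the shortest of 5 classes of genes by exonic length and -0.32 in the longest, against 0.02 and 0 in knockdown library 2. The median exonic lengths of the oxidative phosphorylation and ribosomal protein lists were 1908 and 1781 bases. Genes of nuclear speckle proteins and SR splicing factors, with a median of 6974 bases, had a median log2 difference of -0.12 (-0.21 and -0.07) over 32 members, with 0 called over all genes and 0 adjusted over the list alone. Sf3b1, a core protein of the spliceosome, was at 483 ± 3.16 and 312 ± 54.0 CPM (SD, n = 2 each). This list passed by camera (adjusted p = 0.0116; adjusted p = 0.801 with an estimated correlation), but not without knockdown library 1 (median -0.07, adjusted p = 0.0573, in a range of 0.000246 to 0.228). Its median was -0.20 without knockdown library 2, -0.06 with library size only and -0.065 with upper-quartile factors. With the offsets for exonic length and GC content the oxidative phosphorylation (adjusted p = 0.139), ribosomal protein (0.415), stress response (0.343), speckle (0.228) and neutrophil marker lists (0.203) did not pass by camera, while the macrophage identity list passed on the lower side (0.0322). The oxidative phosphorylation median was then 0.095, against 0.211 in the main fit. The stress response median turned sign, from 0.102 to -0.032.

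**Figure D3:**
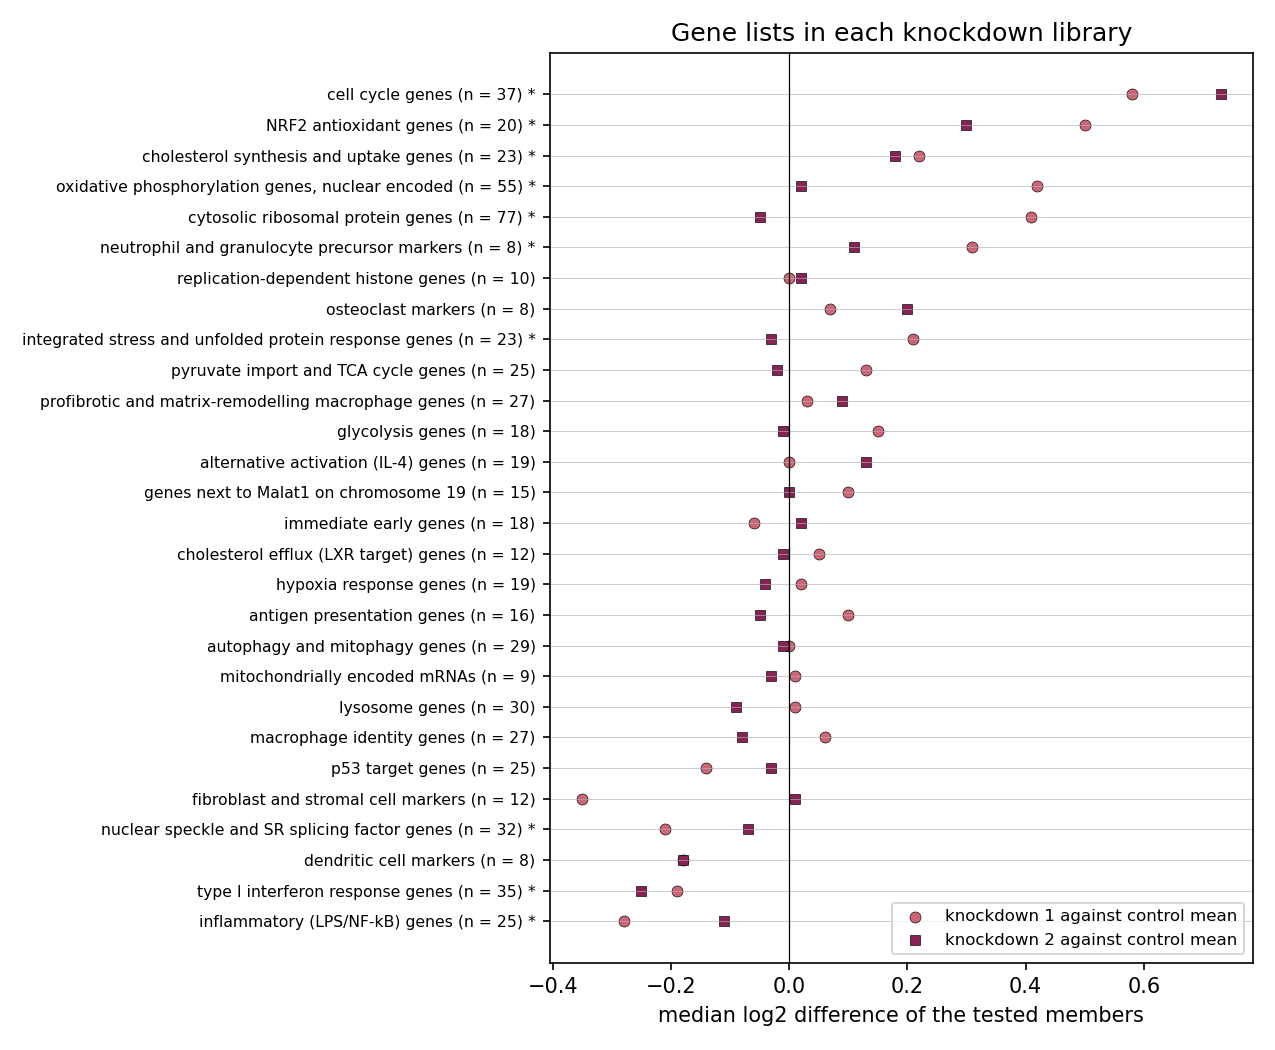
Median log2 difference from the control mean of the tested members of each of 28 gene lists, in knockdown library 1 (circles) and knockdown library 2 (squares); an asterisk marks the 10 lists past the threshold by camera with a preset correlation, and n is the number of tested members. Cell cycle genes lie at 0.58 and 0.73, while oxidative phosphorylation genes lie at 0.42 and 0.02.

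**Figure D4:**
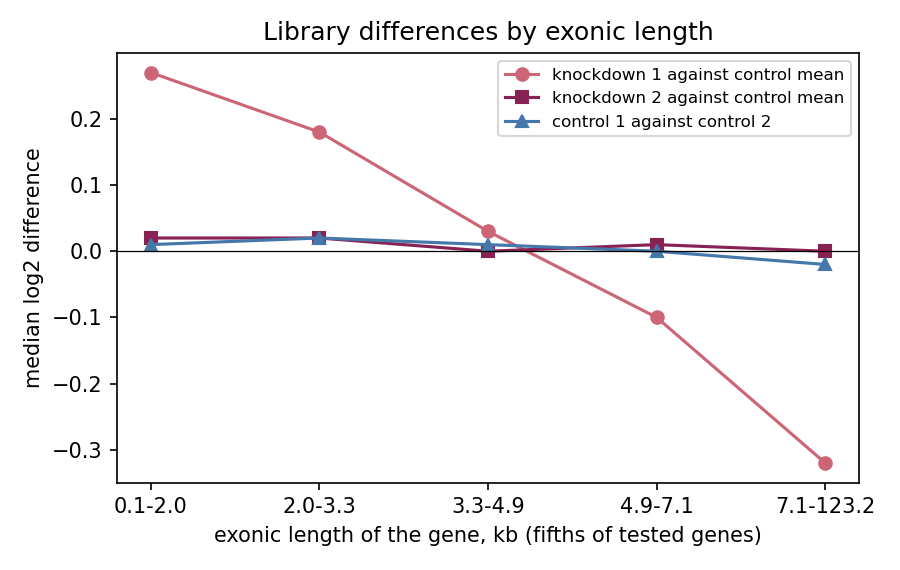
Median log2 difference of the genes in 5 equal classes of exonic length (kb), for each knockdown library against the control mean and for control library 1 against control library 2. Knockdown library 1 goes from 0.27 to -0.32 with length, and the other lines stay between -0.02 and 0.02.

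Macrophage programmes showed few calls. Of 27 macrophage identity genes 0 were called over all genes and 0 adjusted over the list alone, with a median log2 difference of -0.05 (camera, adjusted p = 0.653; 0.0322 with the offsets, in a range of 0.0216 to 0.874 over the alternatives). Adgre1, which encodes the surface marker F4/80, was at 3822 ± 110 CPM in control and 3184 ± 409 CPM in knockdown cells (SD, n = 2 each). The 19 tested genes of alternative activation by interleukin-4 also had 0 calls by either adjustment (median 0.07, adjusted p = 0.787), with Mrc1 at 1767 ± 86.0 and 1335 ± 317 CPM (SD, n = 2 each). Of 27 profibrotic and matrix-remodelling genes the cathepsin K gene Ctsk rose, from 2.28 ± 0.0980 to 6.31 ± 1.25 CPM (SD, n = 2 each, log2 rise 1.46, adjusted p = 0.0423), and 2 rose when adjusted over the list alone. Ctsk did not pass with limma-voom (adjusted p = 0.0554) or with a filter of 5 CPM (0.0787), in a range of 6.93e-09 to 0.0787 over the alternatives. Ctsk starts 2016 bp past the end of Arnt (85.5 CPM) on the same strand. Neither this list nor the 8 osteoclast markers, in which Ctsk was also the call over all genes and over the list alone, passed by camera (adjusted p = 0.179 for each; medians 0.10 and 0.11). The osteoclast median was 0.05 without knockdown library 2, 0.06 without control library 1, 0.33 without control library 2 and 0.31 with no filter on low counts. Of 29 autophagy and mitophagy genes 2 fell over all genes and 2 adjusted over the list alone, Clec16a among them, while the list had a median of -0.02 (camera, adjusted p = 0.223).

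Lysosome genes (30 members, median -0.05, adjusted p = 0.432) and antigen presentation genes (16, median -0.02, mean 0.01, on the lower side by camera, adjusted p = 0.9) had 0 calls by either adjustment. Without knockdown library 1 the camera test was passed by the macrophage identity (adjusted p = 0.0216, in a range of 0.0216 to 0.874), profibrotic (0.0105, 0.00566 to 0.544), autophagy (0.0483, 0.0483 to 0.974), lysosome (0.0113, 0.0113 to 0.763) and antigen presentation lists (0.0251, 0.0251 to 0.97). The profibrotic list, at a median of 0.09 without knockdown library 1, also passed with a filter of 5 CPM (median 0.14, adjusted p = 0.00566). It passed without knockdown library 2 as well (0.0464), though at a median of 0.004. Among the metabolic lists, pyruvate import and tricarboxylic acid cycle genes (25, median 0.10, adjusted p = 0.573), glycolysis genes (18, 0.07, 0.715), mitochondrially encoded mRNAs (9, -0.02, 0.683) and hypoxia response genes (19, 0.02, 0.715, on the lower side by camera) had 0 calls by either adjustment. The lactate exporter gene Slc16a3 was at 34.0 ± 1.55 and 47.8 ± 4.21 CPM and the glycolytic regulator gene Pfkfb3 at 77.4 ± 0.860 and 53.1 ± 9.80 CPM (SD, n = 2 each).

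Of 12 cholesterol efflux genes 0 were called over all genes, and 1 rose and 1 fell adjusted over the list alone (median 0.02, adjusted p = 0.715). Plin2, which coats lipid droplets, was at 477 ± 18.3 and 750.4 ± 136 CPM, and the sterol transporter gene Abcg1 at 287 ± 6.57 and 208 ± 12.5 CPM (SD, n = 2 each). Of 25 p53 target genes 0 were called over all genes and 1 rose adjusted over the list alone (median -0.07, adjusted p = 0.573), Gadd45a, at 7.52 ± 0.333 and 14.2 ± 1.61 CPM (SD, n = 2 each). The 18 immediate early genes had 0 calls over all genes and 1 fall adjusted over the list alone, that of Jun, from 123 ± 0.0738 to 86.2 ± 1.27 CPM (SD, n = 2 each). Their median was 0.03, their mean -0.03, and camera placed them on the lower side (adjusted p = 0.715). The 10 tested histone genes had 0 calls by either adjustment (median 0.11, mean -0.02, on the higher side by camera, adjusted p = 0.98). Leaving out 1 library put the medians of the lists that did not pass, osteoclast and other cell markers apart, between -0.13 and 0.16, and some turned sign.

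Of the markers of other cells that a marrow culture could hold, few passed the test. Of 8 tested markers of neutrophils and their precursors Mmp8 rose, from 4.48 ± 0.574 to 15.0 ± 0.566 CPM (SD, n = 2 each), by either adjustment, and the list had a median log2 difference of 0.18 (0.31 and 0.11). It passed by camera (adjusted p = 0.0272; adjusted p = 0.634 with an estimated correlation), but not without knockdown library 2 (0.292) or control library 1 (0.119), nor with limma-voom (0.158), with no filter on low counts (0.0884) or with the offsets (0.203), in a range of 0.0263 to 0.292 over the alternatives. Its median was 0.075 without knockdown library 1, 0.33 without knockdown library 2, 0.29 without control library 1 and 0.335 without control library 2. S100a8, a calcium-binding protein abundant in neutrophils, was at 1.001 ± 0.0311 and 1.75 ± 0.482 CPM (SD, n = 2 each). Markers of dendritic cells (8 tested, median -0.24, adjusted p = 0.715) and of fibroblasts and stromal cells (12 tested, median -0.12, adjusted p = 0.295) had 0 calls by either adjustment. The dendritic median was -0.03 without control library 1 and -0.12 without control library 2, and the fibroblast median 0.003 without knockdown library 1, -0.35 without knockdown library 2 and -0.18 without control library 1. Lists with under 5 tested members were not tested as lists. The 2 lymphocyte markers had a median of 0.63 and the 3 erythroid and megakaryocyte markers one of 0.65, with 2 members of each higher when adjusted over the list alone, and the mast cell and basophil marker Hdc was at a log2 difference of -0.09. Of these markers Cd79b was at 2.17 ± 0.193 and 3.61 ± 0.560 CPM and Itga2b at 0.555 ± 0.00902 and 2.12 ± 0.828 CPM (SD, n = 2 each). Itga2b starts 5793 bp past the end of Gpatch8 on the same strand. A total of 25 lists had 0 calls over all genes by edgeR's quasi-likelihood test, and held 526 different tested genes. Of these, 67 had an unadjusted p under 0.05, while DESeq2 called 16 and limma-voom 0. Over all genes, 1779 of 13706 had an unadjusted p under 0.05 and DESeq2 called 344 of 14536. The shares by these 2 measures were thus near those of all genes. The 16 genes that DESeq2 called in these lists included 3 NRF2 targets, 2 interferon response genes, 2 speckle genes and 2 stress response genes.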

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

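The offsets for exonic length and GC content, and the share of risen genes with an expressed gene upstream under each setting, were chosen only after the data were seen. Malat1 kept its fall and its side of the threshold in all 14 alternatives, at log2 values from -5.61 to -5.28. The 134 changed genes became 1052 with no filter on low counts, 25 with a filter of 5 CPM (9644 genes tested, 60 of the 134 not among them), 344 with DESeq2, 364 with the offsets, 8 at an adjusted p under 0.01, 306 under 0.1 and 75 against a minimum fold of 1.2. Leaving out 1 library gave 174 to 6751 genes. The 2 highest counts, 1812 and 6751, came without a knockdown library, when the spread rests mainly on the control pair. The other scalings, limma-voom and the robust fit gave 113 to 153 genes. Of the 134 genes, 0 changed sign in the settings that tested them. The libraries share numbers across groups, but with 2 pairs and a correlation of 0.07 between deviations the numbers are not shown to pair them. With the replicate number as a block 805 genes passed, all 134 among them, and 10 lists. The 10 lists past the threshold became 6 with the offsets, 5 of them among the 10, 0 with an estimated correlation and 0 with fry (at an unadjusted p under 0.05, 1 and 6 lists). By fry's mixed test 4 lists passed, the cell cycle, inflammatory, immediate early and neutrophil lists (adjusted p = 0.0418 each). Without knockdown library 1 the oxidative phosphorylation list lost its call and its direction by camera (median 0.02, adjusted p = 0.924) and the ribosomal protein list reversed (median -0.05, adjusted p = 0.0434), against highest medians of 0.421 and 0.423 without knockdown library 2; the cause was not tested beyond the offsets. Signs of differences that did not pass in any setting were not counted. Scaling moved the median of all genes by at most 0.07. The share of risen genes with an expressed gene upstream, 63%, was 19% without knockdown library 2, 24.1% without knockdown library 1, 33.8% with no filter, 35% with the block, 39.9% with the offsets, 42.8% with DESeq2 and 43.8% with the stricter filter. Depth limits genes at a low CPM, and 1.5-fold changes were mostly missed in simulated data (31.3% recovered). Recovery was not split by CPM. It may be lower in the data, as simulated genes had no variation of their own around the dispersion trend.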

Other observations

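The test of transcription running on from upstream genes and the offsets for exonic length and GC content were chosen only after the result was seen, as were the genes named in the next 2 paragraphs.

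Of the genes that rose outside the fixed lists, 8 are described as single genes, with no test of them as a group. They were picked from the 102 risen genes by no rule fixed beforehand, so they are not separate support for the cell cycle list. Cenpa, the centromeric histone variant, went from 43.0 ± 2.46 to 80.6 ± 1.74 CPM (SD, n = 2 each, log2 rise 0.91, adjusted p = 0.0313), and Racgap1, which acts in cytokinesis, from 13.5 ± 0.622 to 26.3 ± 1.86 CPM (SD, n = 2 each, log2 rise 0.96, adjusted p = 0.038). The kinase gene Nek2 rose by a log2 of 1.17 (adjusted p = 0.038), Dlgap5 by 1.15 (0.035), Nuf2 by 0.98 (0.0492), Kif22 by 1.01 (0.0459), Fbxo5 by 0.93 (0.0459) and the phosphatase gene Cdc25b by 0.73 (0.0459), all by edgeR's quasi-likelihood test. Of these genes Cenpa has an expressed gene within 10 kb upstream.

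Of the genes that fell, 4 outside the fixed lists are likewise given as single genes. Fpr2, which encodes a formyl peptide receptor, went from 24.6 ± 0.0967 to 11.6 ± 0.425 CPM (SD, n = 2 each, log2 -1.08, adjusted p = 0.0242). Slamf9 went from 187 ± 23.4 to 93.5 ± 14.2 CPM (adjusted p = 0.048), Siglece from 51.1 ± 0.264 to 29.3 ± 0.523 CPM (adjusted p = 0.038) and the complement regulator gene Cd55 from 23.0 ± 0.135 to 11.2 ± 1.67 CPM (SD, n = 2 each, adjusted p = 0.0435). Igsf9, which fell as well, starts 3213 bp past the end of Slamf9 on the same strand.

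Genes that rose from a low level mostly lay just downstream of an expressed gene, though among all risen genes the share was 24.1% without knockdown library 1 and 19% without knockdown library 2, when many more genes were called. Of the 100 risen genes with an annotated position 63% had a gene at 20 CPM or more ending within 10 kb upstream on the same strand. The share was 10% (95% range 5 to 16) of unchanged genes matched on expression (permutation p = 1e-04, the smallest that 10000 draws can give). Downstream genes on the same strand gave 11%, inside the matched range of 3 to 14 (permutation p = 0.2). Downstream genes on the other strand gave 17%, just above the matched range of 5 to 16 (permutation p = 0.02). As strandedness was not given, reads from that strand could be counted too. Other distances and levels gave 43% to 71% upstream against upper bounds of 8 to 26. Genomic DNA or unspecific reads, which would lift all low genes, are argued against by the uncalled genes under 2 CPM with no such upstream gene (median log2 0.07, 95% interval 0.04 to 0.09, n = 2547), and cells of another type as the whole cause by the highest median of their marker lists (0.65 over 3 genes, 0.18 among lists of 5 or more), by 7 genes of red cells, lymphocytes and basophils (globins, Cd79a, Cd3e and Mcpt8) at 0.17 CPM at most in knockdown cells, and by the neutrophil genes S100a8, at 1.75 CPM there against 43.4 CPM for Mybpc3, and S100a9, at a log2 difference of 0.24. A small share of other cells stays open, since the neutrophil list passed by camera (adjusted p = 0.0272), with Mmp8 at 4.48 and 15.0 CPM and Ngp at 3.29 and 4.27 CPM in control and knockdown cells, and Cd79b (2.17 and 3.61 CPM) and Itga2b (0.555 and 2.12 CPM) were higher too. Transcription running on past the ends of upstream genes in the knockdown cells may account for many of these rises. Uncalled low genes with an upstream gene had a median of 0.50 (95% interval 0.37 to 0.59, n = 289), at 0.50 and 0.48 in the 2 libraries. Of the 63 upstream genes 0 were called (median -0.04). Reads in no annotated feature made up 6.43% and 6.41% of all counts in control libraries 1 and 2. They made up 5.34% and 6.77% in knockdown libraries 1 and 2, so they were not higher in both. This share pools all reads outside the counted features, so it cannot decide the question. Whether such transcription comes from loss of Malat1 or from the oligonucleotide itself was not tested, as 1 knockdown reagent is named and its sequence is not given.

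Genes that fell were long. The median span of the 31 fallen genes other than Malat1 was 88.8 kb, against 24.9 kb (95% range 16 to 39.2) for unchanged genes matched on expression and exonic length (permutation p = 1e-04, the smallest that 10000 draws can give), and 45.2% of them exceeded 100 kb against 10.7% of unchanged genes. A bias against long mature transcripts or by GC content is argued against as the whole cause, since 96.8% of them still passed with the offsets (median log2 -1.21 before and -1.18 after, median SE 0.16 and 0.13). An effect that grows with the unspliced length may be involved, whether through loss of Malat1 or through binding of the oligonucleotide within introns, and without its sequence these stay untested. Fpr1, Fpr2, Socs3 and Slamf9, which span 7470, 6129, 3969 and 3218 bp, fell too.

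The 2 knockdown libraries differed from each other by over 2-fold in 551 genes, against 303 for the controls. Offsets for exonic length and GC content left 529 such genes. The median difference between these libraries went only from 0.25 to -0.33 with exonic length, so a 2-fold count could show little of such a bias. With the offsets the median absolute difference went from 0.26 to 0.18, against 0.09 between the controls. The bias may thus be part of the difference, and what remained argues against it as the whole cause. A stronger effect of the oligonucleotide in knockdown library 1 could not be told apart from other differences: 69.2% of the 133 called genes other than Malat1 lay further from control there, with medians of 1.84 and 1.77, and Malat1 itself was at 24.6 and 31.0 CPM. The labels give no batch or date for these libraries.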
